A study of Mus musculus with 6 samples.

How the data were processed

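RNA was sequenced from lineage-negative, c-Kit-positive cells of mouse bone marrow, a sorted fraction that holds stem cells and early progenitors. The 6 libraries were 3 from control mice and 3 from copper-deficient mice. The control titles call the mice wild type, the other titles give no genotype, and how the deficiency was brought about is not given in the sources used here. The titles of all libraries also give 5 weeks, and whether this is an age or a duration of treatment is not given in the sources used here. Total RNA was extracted with Trizol and made into Illumina libraries, per the labels' protocols. Whether the libraries keep the strand of the RNA is not given in the sources used here.

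The authors deposited 1 table with the FPKM of each gene in each library, that is, fragments scaled to the length of the gene and the depth of the library. The submitters' processing notes name the genome build mm9 and CASAVA 1.7. The aligner, the counting program, the annotation and the gene lengths are not given in the sources used here. All 6 value columns were matched to a sample by the short name in its description. Genes are named in the table by Ensembl identifiers. Of 26169 identifiers, 26073 were matched without their version to symbols of the GENCODE M21 annotation, and 96 had no match. Because that annotation belongs to a later build than the one in the notes, it was used for names and gene types, and no coordinates are given.

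Depth was read from the values. After division by a relative depth per library, the values of a gene were whole multiples of 1 step for 23018 of the 23019 genes above 0 in at least 2 libraries, at a relative tolerance of 1e-09. The deposited FPKM values had therefore come from whole reads per gene. The recovered reads summed to between 15181811 and 18036084 per library. These are the smallest whole numbers with the ratios seen. They leave out 3150 genes above 0 in 1 library, so the sums are lower bounds. The same steps applied to 5000 simulated genes returned the exact reads of 98.2% of those with at least 100 reads.

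Groups and replicate numbers were taken from the sample titles. Nothing in the sources used here says how many mice gave each library, so p-values measure the spread between these libraries. No pair of libraries within a group agreed within sampling noise. The chi-square per degree of freedom of recovered reads was 10.7 to 36.1 for the 6 pairs. It covers the sampling of reads only, so it cannot tell separate mice from separate libraries of the same RNA. Sex-linked genes do tell some apart. Xist was at 0.03 and 42.88 FPKM in control replicates 1 and 3, and at 0 and 53.41 in copper-deficient ones. The Y-linked gene Ddx3y was at 23.08 and 0 FPKM, and at 11.8 and 0.01. Replicates 1 and 3 of a group were therefore not libraries of the same RNA. Each library was counted as 1 replicate, as the titles number them.

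Genes with a mean FPKM of at least 1 over the 6 libraries were tested. Values were transformed to log2(FPKM + 1), which understates the change of low genes, and every log2 fold change is on this scale. The groups were compared with limma 3.58.1 in R 4.3.3, with moderated variances, a trend in the variance prior and no covariates. P-values were two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. The 38 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Camera compares a list with the other genes. Fry asks whether the members of a list move, on balance, in 1 direction.

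On simulated data for the comparison of copper deficiency with control, 200 of 11792 genes were changed. The test called 83% of genes changed by 1 log2 unit and 92% of those changed by 2, and 6.4% of its calls were unchanged genes. The simulated genes were independent of each other, and far fewer were changed than the 52.1% called in the data. These shares therefore need not hold for the data.

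The lists, tests, alternatives and rule for named genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest log2 fold changes among genes past the threshold whose groups did not overlap. It left out, by their symbols, unnamed gene models, genes starting with Mir or Snor, antigen receptor segments and pseudogenes named as such. It also took up to 4 members of each list with the smallest p, and genes of copper handling plus Kit as checks. Any other gene named was chosen after its values were seen. Sco2 and Mt2 are not analysed here.

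Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, a variance prior without trend, a replicate block, and each library left out in turn. After the data had been seen, limma's voom on the recovered reads and the ribosomal protein list without 4 genes were added. Processed pseudogenes were aligned to coding transcripts with blastn 2.17.0, at over 95% identity over more than 70% of the pseudogene.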

Results

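The series compared bone marrow cells of copper-deficient mice with those of control mice, to ask how a lack of copper changes gene expression in blood stem and progenitor cells. The cells had been sorted as lacking lineage markers and carrying c-Kit, the receptor for stem cell factor. There were 3 libraries per group. The reads recovered from the FPKM values summed to 15181811, 16810781 and 17137273 in control replicates 1, 2 and 3, and to 17761111, 18036084 and 17692068 in copper-deficient replicates 1, 2 and 3. Between 20559 and 21128 genes were above 0 in a library.

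Copper deficiency went with a wide change in expression. Most erythroid, heme synthesis, ATF4-response and mitochondrial ribosomal protein genes rose, while most NF-kB, neutrophil, megakaryocyte, B-lineage and stromal genes fell. Of 11792 genes tested with limma, 3453 were higher and 2685 lower in copper deficiency, together 52.1% of those tested. By at least 1 log2 unit, 560 were higher and 541 lower. The groups did not overlap in 3430 of the higher and 2662 of the lower genes, and in 61.9% of all tested genes, where chance gives 10%. The first principal component held 72.7% of the variance and separated the groups. Correlations of log values across genes were 0.970 to 0.983 between libraries of 1 group and 0.905 to 0.933 between groups. With camera, 23 of the 38 lists were called. With an estimated correlation between genes, none of the 38 was called, and the lowest adjusted p was 0.589. Fry called 25 of them. With only genes of a mean FPKM of at least 5, the calls of the lipoylation (0.109), cytochrome c oxidase (0.0563), macrophage (0.103), dendritic (0.179), lymphoid progenitor (0.109), cell cycle inhibitor (0.075) and sterol (0.0906) lists were lost, and the T and NK cell and stromal lists had too few members to be tested. Without the filter, those of the sterol (0.079) and cell cycle inhibitor (0.073) lists were lost, and with quantile normalization those of the dendritic (0.0732) and T and NK cell (0.0547) lists. Median-of-ratios scaling ended the dendritic call (0.0667).

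Kit, used as a check of the sort, was at 14.2 ± 0.556 FPKM in control and 16.5 ± 1.54 in copper deficiency (SD, n = 3), a difference that did not pass the test (adjusted p = 0.0922). It passed when copper-deficient replicate 1 was left out (adjusted p = 0.0212). Transcripts of neutrophil granules were nonetheless among the most abundant in both groups. The calcium-binding protein gene S100a9, a neutrophil list member outside the rule for named genes and chosen after its values were seen, was at 26710 ± 937 FPKM in control and 17150 ± 1915 in copper deficiency. Ly6g, a member chosen in the same way, was at 130.8 ± 8.46 FPKM in control and 77.3 ± 4.76 in copper deficiency. It was thus above Kit in both groups, so the libraries held much neutrophil RNA beside that of progenitors.

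Some genes of copper handling rose and others did not pass the test. The metallothionein gene Mt1 went from 85.7 ± 7.496 to 243 ± 28.1 FPKM (log2 fold change 1.49 ± 0.11 SE, adjusted p = 0.000228). Atp7b, a copper-exporting ATPase, went from 1.65 ± 0.725 to 9.52 ± 0.730 FPKM (log2 fold change 2.03, adjusted p = 0.000396). Sod1, the copper-zinc superoxide dismutase, rose by 0.84 log2 units, and Ccs, the chaperone that loads it with copper, rose by 1.38. Slc31a2, a transporter related to the copper importer, fell by 0.77 and the metalloreductase gene Steap3 rose by 1.65. The importer gene Slc31a1 had a log2 fold change of -0.29 (adjusted p = 0.0788), the ATPase gene Atp7a -0.37 (adjusted p = 0.1) and the chaperone gene Atox1 -0.42 (adjusted p = 0.153). Slc31a1 passed without copper-deficient replicate 2 (adjusted p = 0.0219) and with median-of-ratios scaling (0.0443) or quantile normalization (0.0444), Atp7a with voom (0.0425), and Atox1 without copper-deficient replicate 1 (adjusted p = 0.00537). Sco1, a copper chaperone of cytochrome c oxidase, was 0.30 higher (adjusted p = 0.029), and lost the call when any library except copper-deficient replicate 1 was left out, with adjusted p from 0.0664 to 0.103. It was also lost without the filter (0.0594) and with median-of-ratios scaling (0.0766) or quantile normalization (0.0874). Cox17, at 0.967 ± 0.119 FPKM in control and 0.269 ± 0.0211 in copper deficiency, and Cp, at 0.0823 and 0.158, lay below the filter. Of 17 copper-handling genes tested, 8 rose and 1 fell, and the counts adjusted over the list alone were also 8 and 1. The list was not called (camera adjusted p = 0.0759, and 0.589 with an estimated correlation), except without control replicate 1 (adjusted p = 0.0474), without the filter (0.0416) and with fry (0.0116).

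Erythroid genes rose nearly together. Of 32 tested, 28 rose and 1 fell, with a median log2 fold change of 1.49 (camera adjusted p = 2.79e-07, and adjusted p = 0.589 with an estimated correlation). Car1, carbonic anhydrase 1, went from 118 ± 53.5 to 1119 ± 279 FPKM (SD, n = 3; log2 fold change 3.29 ± 0.33 SE, adjusted p = 0.000493). Tal1, a transcription factor of early blood development, rose by 1.63, Epor, the erythropoietin receptor, by 2.11, and the membrane protein gene Epb41 by 0.85. The member that fell was Nfe2, a transcription factor shared with megakaryocytes (log2 fold change -0.51), named after its values were seen. Adjusted over the list alone, the counts were also 28 and 1. Of 21 heme synthesis genes, 15 rose and 1 fell (median 0.68, camera adjusted p = 0.00467, and adjusted p = 0.589 with an estimated correlation), the same counts as adjusted over the list alone. They included Cpox, coproporphyrinogen oxidase, which went from 22.3 ± 7.48 to 134 ± 25.6 FPKM (log2 fold change 2.56). Iron handling was mixed, with 5 of 15 genes higher and 2 lower, also adjusted over the list alone. It was not called by camera (adjusted p = 0.533), but was by fry (adjusted p = 0.024). Tfr2, a transferrin receptor of erythroid cells and liver, rose by 2.21, and Fbxl5, an iron sensor that targets iron regulatory proteins for degradation, fell by 1.07.

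Genes of the other blood lineages mostly fell. None of 33 neutrophil genes rose and 23 fell, also adjusted over the list alone (median -0.46, camera adjusted p = 1.15e-06). The granule and maturation genes Retnlg (1598 ± 190 to 564 ± 25.01 FPKM, log2 fold change -1.49), Mmp8 (-1.38), Mmp9 (-1.07) and Padi4 (-0.72) were among them. Of 20 megakaryocyte genes, 13 fell and none rose, with 16 falling when adjusted over the list alone (median -0.77, camera adjusted p = 6.34e-05). Thbs1, the platelet protein thrombospondin 1, went from 179 ± 28.7 to 13.8 ± 0.780 FPKM (log2 fold change -3.60 ± 0.12 SE, adjusted p = 4.27e-05), and Plek, a protein kinase C substrate of platelets, fell by 1.48. Of 20 monocyte genes, 12 fell and 3 rose, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0175). Klf4, a regulator of monocyte differentiation, fell by 0.93 and Ms4a6c by 0.94. With an estimated correlation the adjusted p was 0.589 for each of these 3 lists. Of 18 mast cell, basophil and eosinophil genes, 1 rose and 5 fell, or 1 and 4 over the list alone, and the list was not called (camera adjusted p = 0.128) except with fry (0.0176) and without control replicate 1 (0.0379). Prss34, a basophil protease, fell by 1.17.

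Apart from the neutrophil genes, markers of other cells that the sort should remove also differed. Of 19 B-lineage genes, 15 fell and none rose, with 17 falling adjusted over the list alone (median -1.24, camera adjusted p = 1.15e-06). Cd79a, a chain of the B cell receptor complex, went from 30.3 ± 9.80 to 9.50 ± 0.811 FPKM (log2 fold change -1.54). Immunoglobulin segments, a gene type looked at after the values were seen, did not all follow. Of 150 variable segments tested, 32 rose and 4 fell (median 0.75), and of 10 joining segments none rose and 4 fell (median -1.60). Of 11 constant-region genes, 5 rose and 2 fell (median 0.29). Variable segments resemble each other, so their separate values are uncertain. Of 10 stromal and endothelial genes, 7 fell and 1 rose, also over the list alone (median -1.58, camera adjusted p = 0.00467). The bone matrix genes Col1a1 (24.5 ± 7.56 to 1.18 ± 0.356 FPKM, log2 fold change -3.52) and Sparc (-2.51) fell. So did the osteocalcin genes Bglap (-2.54) and Bglap2 (-2.49), which are close copies, so their separate values are uncertain. The gene that rose was Fabp4, a fatty acid binding protein, at 0.813 ± 0.14 FPKM in control and 3.16 ± 0.330 in copper deficiency. Of 8 T and NK cell genes, 3 fell and none rose, also over the list alone (camera adjusted p = 0.0335). That call was lost without copper-deficient replicate 1 (0.0691) or 3 (0.0507). Of 10 dendritic cell genes, 6 fell and 2 rose, or 7 and 2 over the list alone (camera adjusted p = 0.0441). It was lost without copper-deficient replicate 1 (0.0773) or 3 (0.0536). Cd74, the invariant chain of class II antigen presentation, fell by 1.84. Tissue macrophage genes went the other way, with 10 of 13 higher and 1 lower, or 11 and 1 over the list alone (median 0.73, camera adjusted p = 0.0213). That call was lost without copper-deficient replicate 2 (0.0524). C1qa, a complement chain, went from 14.4 ± 4.12 to 42.1 ± 7.504 FPKM, and Apoe rose by 1.26. With an estimated correlation, the adjusted p was 0.589 for the B-lineage, stromal, T and NK, and dendritic lists and 0.649 for the macrophage list.

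Stem and multipotent progenitor genes moved in both directions. Of 19 tested, 4 rose and 6 fell, also over the list alone, and the list was not called (camera adjusted p = 0.482). Cd34, a surface marker of progenitors, went from 9.44 ± 0.553 to 3.10 ± 0.674 FPKM (log2 fold change -1.36 ± 0.13 SE, adjusted p = 0.000405). Gfi1b, a repressor used in stem, erythroid and megakaryocyte cells, rose by 1.91 and Mllt3 by 0.97. Of 19 lymphoid-primed progenitor genes, 11 fell and 3 rose, also over the list alone (camera adjusted p = 0.0175). They included the receptor gene Notch1 (-1.30) and the chemokine receptor gene Ccr7 (-2.42) among those lower and the transcription factor gene Bcl11a (1.26) among those higher. Of 14 cell cycle inhibitor genes, 7 fell and 1 rose, also over the list alone (camera adjusted p = 0.0306). The call was lost without copper-deficient replicate 1 (0.0632). Cdkn1a, which encodes the inhibitor p21, fell by 1.24 and Foxo1 by 1.07. With an estimated correlation the adjusted p was 0.589 for both of these called lists.

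Most NF-kB and cytokine genes fell. None of 25 rose and 19 fell, also over the list alone (median -1.13, camera adjusted p = 2.25e-08, and adjusted p = 0.589 with an estimated correlation). The inhibitor and target gene Nfkbia went from 865 ± 22.1 to 339 ± 10.4 FPKM (SD, n = 3; log2 fold change -1.35). The subunit genes Relb and Nfkb2 fell by 1.95 and 1.55, and the cytokine gene Il6 by 2.02. Nlrp3, the inflammasome sensor, went from 46.3 ± 0.711 to 3.70 ± 2.16 FPKM (log2 fold change -3.43), and Rel, another subunit, fell by 2.85. Interferon response genes were not called, with 4 of 37 higher and 4 lower, or 1 and 3 over the list alone (camera adjusted p = 0.647). Irf1 fell by 1.53. Immediate early genes, which respond to the handling of cells, split, with 6 of 25 higher and 7 lower, also over the list alone (camera adjusted p = 0.647). Fosl2 fell by 2.20, while Myc rose by 1.34.

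**Figure D1:**
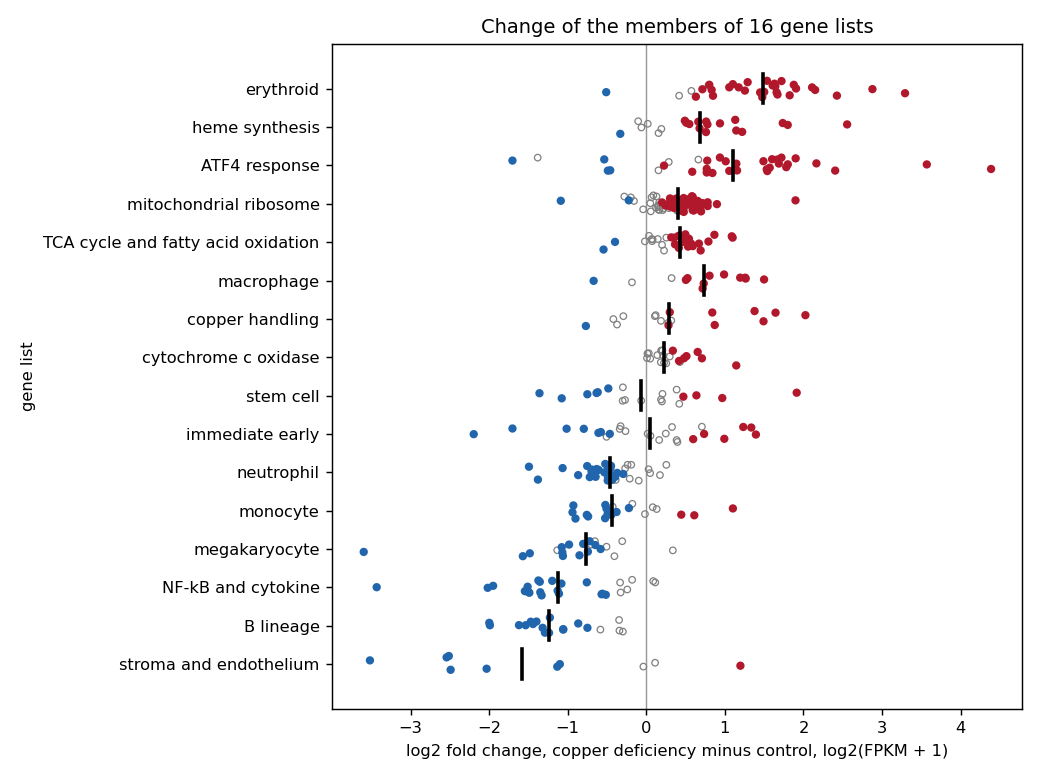
Log2 fold change of the tested members of 16 lists, copper deficiency minus control on the log2(FPKM + 1) scale; each point is a gene, filled red or blue if past the limma threshold and open if not, and black lines are list medians. Erythroid members lie mostly right of 0 around a median of 1.49, and NF-kB members mostly left of 0 around a median of -1.13.

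Genes of the ATF4 response, which supplies amino acids and loads transfer RNAs under stress, rose. Of 34 tested, 26 rose and 4 fell, or 27 and 5 over the list alone (median 1.10, camera adjusted p = 6.94e-07, and adjusted p = 0.589 with an estimated correlation). Cth, which makes cysteine from cystathionine, went from 0.129 ± 0.0767 to 22.7 ± 2.21 FPKM (log2 fold change 4.39 ± 0.10 SE, adjusted p = 9.31e-06). The pseudokinase gene Trib3 rose by 3.57, the serine synthesis gene Psat1 by 1.60 and the glycyl-tRNA synthetase gene Gars by 1.53. The 4 members that fell were Atf3, Slc7a11, Ddit3 and Atf4 itself. The last 3 were chosen after their values were seen. Atf4 went from 515 ± 34.1 to 374 ± 18.4 FPKM (log2 fold change -0.46) and Ddit3 fell by 0.49. Some genes of the unfolded protein response in the endoplasmic reticulum fell, with 9 of 21 lower and none higher, also over the list alone. The list's camera adjusted p was 0.00541, and its adjusted p was 0.633 with an estimated correlation. Xbp1 fell by 0.57 and Herpud1 by 0.91. Of 37 autophagy and lysosome genes, 17 fell and 3 rose, also over the list alone (camera adjusted p = 0.00297, and adjusted p = 0.589 with an estimated correlation). The cargo receptor gene Sqstm1 fell by 1.16 and the kinase gene Ulk1 by 1.23. Of 23 sterol genes, 9 fell and 2 rose, also over the list alone. Srebf2, a transcription factor of sterol genes, went from 35.2 ± 3.25 to 19.6 ± 1.86 FPKM. The sterol list was called (camera adjusted p = 0.048, and adjusted p = 0.589 with an estimated correlation), but not without control replicate 1 (0.111) or without copper-deficient replicate 1 (0.0501), 2 (0.0524) or 3 (0.0577).

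In 3 lists of mitochondrial genes encoded in the nucleus, most members rose, by small amounts. Of 76 mitochondrial ribosomal protein genes, 48 rose and 2 fell, or 51 and 2 over the list alone (median 0.40, camera adjusted p = 1.51e-06). Mrpl52 rose by 1.90 and Mrps23 fell by 1.09. Of 32 genes of the tricarboxylic acid cycle and fatty acid oxidation, 21 rose and 2 fell, or 23 and 2 over the list alone (median 0.43, camera adjusted p = 0.000243). Acadl, a dehydrogenase of fatty acid oxidation, rose by 0.87, and Dlst, a subunit of the oxoglutarate dehydrogenase complex, fell by 0.54. Of 15 genes for lipoylated enzymes and iron-sulfur clusters, 9 rose and 1 fell, also over the list alone (camera adjusted p = 0.0335, and 0.0909 without copper-deficient replicate 1). Nfs1, the cysteine desulfurase, rose by 1.01. For these 3 lists the adjusted p was 0.589 with an estimated correlation.

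Some nuclear-encoded genes of cytochrome c oxidase, the copper enzyme of the respiratory chain, rose. Of 21 tested, 7 rose and none fell, with 5 rising over the list alone (median 0.23, camera adjusted p = 0.030, and adjusted p = 0.719 with an estimated correlation). They included Lrpprc, which stabilises mitochondrial transcripts (7.49 ± 0.473 to 17.8 ± 1.41 FPKM, log2 fold change 1.15), and the heme A synthesis genes Cox15 (0.65) and Cox10 (0.48). Of 64 genes of the other respiratory complexes and ATP synthase, 26 rose and 2 fell, or 21 and 1 over the list alone (median 0.28, camera adjusted p = 0.00911, and adjusted p = 0.720 with an estimated correlation). Ndufs1 of complex I rose by 0.93. Both calls were lost without copper-deficient replicate 1 (0.161 for cytochrome c oxidase, 0.251 for the others). Fry called neither (0.0611 and 0.0927). Of 12 protein genes of the mitochondrial genome, 1 rose, none over the list alone (camera adjusted p = 0.482). That gene was mt-Co1, a catalytic subunit of cytochrome c oxidase (8350 ± 1301 to 14160 ± 1593 FPKM, log2 fold change 0.77, adjusted p = 0.0131). It lost the call without control replicate 2 (adjusted p = 0.0569) and without the filter (0.557). In control, mt-Co2 (26.3 FPKM), mt-Co3 (23.3), mt-Atp6 (17.5), mt-Nd4l (3.42) and mt-Nd3 (2.20) lay far below mt-Co1 and mt-Cytb (3003). The cause was not tested. These low values may not measure the transcripts fully, so the list result need not hold for the whole mitochondrial genome.

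Some cytosolic ribosomal protein genes rose, with 35 of 80 higher and 2 lower, or 33 and 2 over the list alone (median 0.38, camera adjusted p = 0.000243, and adjusted p = 0.719 with an estimated correlation). Fry did not call the list (adjusted p = 0.0611). The 4 members with the smallest p went apart from the rest and share sequence. Rps3a1 fell from 1152 ± 13.2 to 397 ± 95.4 FPKM (log2 fold change -1.56), while Rps3a2 (99.5% identical) rose from 42.8 ± 3.81 to 744 ± 115 FPKM (4.08). Rps3a3 (98.9% identical) rose from 8.83 ± 1.01 to 436 ± 50.1 FPKM (log2 fold change 5.47, adjusted p = 9.31e-06). Rpl30 fell from 102 ± 0.929 to 25.5 ± 4.94 FPKM (-1.98), while Gm12191 (99.7% identical), chosen after its values were seen, rose from 32.0 ± 0.765 to 740 ± 284 FPKM (4.41). Values of these genes are uncertain, because counting could split or move reads between copies. The small nucleolar RNA gene Rnu73b, which fell by 2.55, lies within Rps3a1 and is uncertain too. Without the 4 genes Rps3a1, Rps3a2, Rps3a3 and Rpl30, 33 of 76 members rose and none fell, with a median of 0.38.

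**Figure D2:**
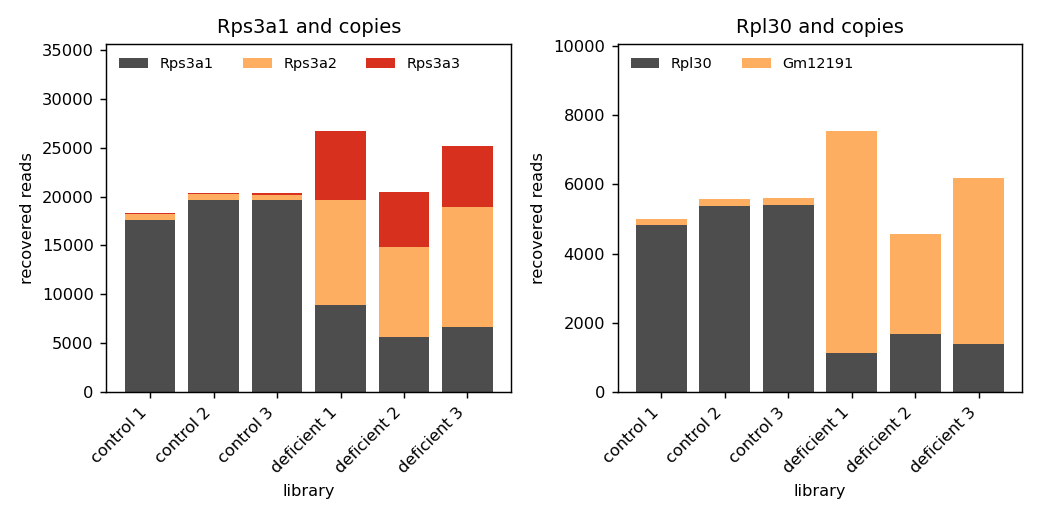
Recovered reads, stacked in each library. The left panel shows Rps3a1 and the copies Rps3a2 and Rps3a3, which rose, and the right panel Rpl30 and the copy Gm12191, which rose. In control replicate 1, 17644 reads were assigned to Rps3a1 and 114 to Rps3a3, and in copper-deficient replicate 1 the numbers were 8886 and 7035.

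Among the remaining large rises were Podxl, a sialomucin of stem cells and vessels, which went from 0.270 ± 0.243 to 50.9 ± 9.78 FPKM (log2 fold change 5.35 ± 0.18 SE, adjusted p = 4.27e-05), Bex4 (4.31) and C2cd4a (4.05). The sodium pump subunit gene Atp1b2 (3.64), the endothelial lipase gene Lipg (3.52), Epdr1 (3.42) and Reep6 (3.30) completed the 12 highest. Among the remaining large falls were the phosphodiesterase gene Pde4b (-3.11), Suco (-2.62) and Zbtb10 (-2.34).

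**Figure D3:**
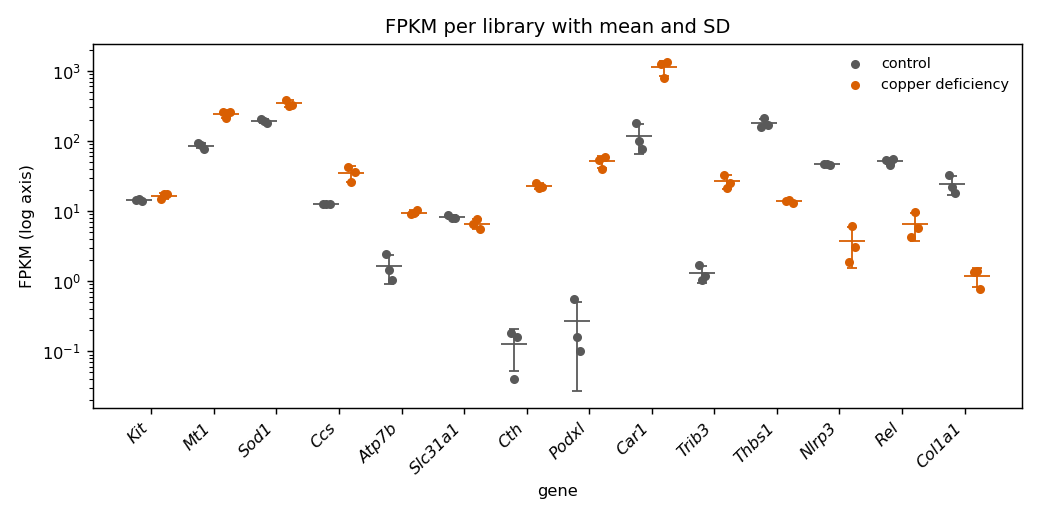
FPKM on a log axis of 14 genes in the 3 control (grey) and 3 copper-deficient (orange) libraries, with horizontal lines for the mean and bars for 1 SD. Kit overlapped in level between the groups, with means of 14.2 and 16.5 FPKM, whereas Cth went from 0.129 to 22.7 FPKM and Thbs1 from 179 to 13.8 FPKM.

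Proliferation and other stress lists were not called by camera. Of 47 mitotic genes, 16 rose and 4 fell, or 16 and 3 over the list alone (camera adjusted p = 0.0759). The list was called without copper-deficient replicate 1 (0.0344), without the filter (0.0014) and with fry (0.0133). Hjurp, a centromere chaperone, fell by 1.28, and the cyclin gene Ccna2 rose by 0.46. Of 44 DNA replication genes, 13 rose and 5 fell, also over the list alone (camera adjusted p = 0.584). Of 47 replication-dependent histone genes, 12 rose and 3 fell, or 11 and 3 over the list alone (camera adjusted p = 0.149, and 0.0175 without the filter). Glycolytic genes went both ways, with 8 of 22 higher and 8 lower, or 8 and 10 over the list alone (camera adjusted p = 0.515). The hexokinase gene Hk1 rose by 1.38 and the glucose transporter gene Slc2a1 fell by 1.38. Of 35 antioxidant genes, 14 rose and 6 fell, or 14 and 7 over the list alone (camera adjusted p = 0.533, fry 0.0176). Gclm, a subunit of the glutathione-synthesis enzyme, rose by 1.42 and Nqo1 by 1.76. Counts of genes higher and lower were 6 and 9 of 28 p53 targets, 3 and 7 of 24 apoptosis genes and 2 and 5 of 17 hypoxia genes, all also over the list alone. Their camera adjusted p were 0.647, 0.517 and 0.517. The p53 targets included Mdm2 (-1.28), the apoptosis genes Birc3 (-1.37) and the hypoxia genes Pdk1 (1.07). For 4 uncalled lists the median, mean and camera differed in sign. Camera gave a downward direction for glycolysis (median -0.06, mean 0.02), interferon (median 0.05, mean 0), p53 (median 0.12, mean -0.06) and immediate early genes (median 0.05, mean -0.01).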

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

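The counts of higher and lower genes stayed within 1.5 times of 3453 and 2685 under all alternatives run. Each library left out in turn gave 2650 to 3436 higher and 2069 to 2671 lower genes. Limma's voom on the recovered reads, chosen after seeing the data, gave 3498 and 2824. Median-of-ratios scaling gave 2933 and 3082, so that 48.8% of calls were higher, against 56.3% as deposited. Of the 6138 calls, 5618 were kept with the same direction under that scaling. With the replicate block, 2864 genes were higher and 2224 lower, and 22 lists were called, without the sterol list (adjusted p = 0.0609). Over all tested genes the shared numbers showed no pairing, although sex-linked genes followed the number in both groups: deviations from the group means correlated at -0.081, -0.151 and -0.023 for numbers 1, 2 and 3, and no number correlated best with its own.

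The number of called lists, 23, fell to 14 when only genes with a mean FPKM of at least 5 were tested, which left fewer members per list and too few to test the called T and NK cell and stromal lists, and to 0 with an estimated correlation. The cause of the latter was not tested. The autophagy and lysosome call was lost although its estimated correlation was 0.009, about the preset 0.01. The size of the correlation between genes therefore does not account for that loss. The number of called lists was 17 to 24 with 1 library left out. The direction of uncalled lists turned without the filter for p53 targets (adjusted p = 0.520), apoptosis (0.943), hypoxia (0.960), interferon (0.828) and immediate early genes (0.960), and the cause was not tested. It also turned for mitochondrially encoded genes without copper-deficient replicate 2 (0.994), for interferon genes without copper-deficient replicate 1 (0.546) and for immediate early genes without control replicate 3 (0.796), again for a cause not tested. Over the 6 libraries left out in turn these 3 lists had adjusted p from 0.173 to 0.994, 0.297 to 0.765 and 0.423 to 0.814. Depths of 15181811 to 18036084 reads limit low genes, such as those under the filter of 1 FPKM.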

Other observations

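The genes in this part were chosen after the values were seen. So were the tests, except list counts in other splits and those on gene length and on the ATF4 slope. The length and slope tests were set before they were run, but for patterns already seen in the results. Of 8 tested genes of serine, one-carbon, proline and amino acid transport metabolism outside the fixed ATF4 list, 7 rose and none fell. They were picked by hand and not tested as a list. They included the proline synthesis genes Aldh18a1 (13.4 ± 1.78 to 51.6 ± 5.70 FPKM, SD, n = 3, log2 fold change 1.87) and Pycr1 (0.815 ± 0.0582 to 3.66 ± 0.689 FPKM), the neutral amino acid transporter gene Slc1a4 (2.63) and the folate enzyme gene Mthfd1l (1.14). Erfe, the erythroid hormone that lowers hepcidin, went from 0.788 ± 0.120 to 9.73 ± 2.16 FPKM (2.57).

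Of 11 tested genes of the circadian clock, 7 fell and 2 rose, where 52.1% of all tested genes passed the threshold. The clock genes were also picked by hand and not tested as a list. Per2 went from 40.1 ± 3.91 to 7.12 ± 0.216 FPKM (log2 fold change -2.33), Per1 fell by 1.49, Bhlhe40 by 1.55 and Cry2 by 0.61. Nr1d1 rose by 0.28 and Tef by 0.36, and Per3 and Arntl did not pass. The hours of collection are not given in the sources used here. The constant-region gene Tcrg-C1 of the T cell receptor gamma chain went from 0.221 ± 0.169 to 54.2 ± 15.9 FPKM (log2 fold change 5.46), while none of 8 T and NK cell genes rose. The small RNA gene model Gm23935 was at 99288, 101248 and 12644 FPKM in control replicates 1, 2 and 3 and at 3810 to 7502 FPKM in copper deficiency, so that 2 control libraries stood apart from the other 4.

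The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 3453 higher and 2685 lower genes, 1 split of the 10 with as many, and the highest of the other splits gave 0 of each. For lists the real split gave 23 calls and the other splits 9 to 24, and 2 of the 10 splits gave at least 23. Every other split mixes both groups, so the real difference adds to the spread within each side. Few gene calls are then possible, so the other splits do not show what chance alone gives.

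Erythroid genes rose while NF-kB genes fell, and technical sources were weighed. Gene length, from recovered reads, does not account for this: with the length trend removed, the median log2 fold change was 1.44 for erythroid and -1.21 for NF-kB genes. A smaller share of neutrophil-lineage cells, if it were the only change, would raise all other lineages alike. However, the median was -0.77 for the megakaryocyte list and 0.73 for the macrophage list. The megakaryocyte list was chosen after its values were seen, and each lineage may also change by itself. A part of the erythroid rise could therefore still come with fewer neutrophil-lineage cells. Fewer mature neutrophils may lower NF-kB genes. The neutrophil list's median was -0.46 against -1.13 for NF-kB, and 2 of 33 neutrophil genes, Retnlg and Mmp8, lay below -1.13. The list mixes such genes with others that barely moved, such as Prtn3 (0.03), Ctsg (0.05) and Cxcr2 (0.17), so its median need not measure mature neutrophils. Fewer mature neutrophils and a response of each cell to copper deficiency cannot be told apart in bulk libraries, and the latter was not tested.

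ATF4 target genes rose although Atf4 itself was lower. A larger share of erythroid cells could carry this rise. Within groups, the mean of the ATF4 list moved by 0.17 per unit of the erythroid mean (95% interval -0.37 to 0.71), against a ratio of 0.76 between groups. With 6 libraries that interval reaches from slopes below 0 to nearly the ratio, so cell share and a stress response in each cell cannot be told apart.

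Rps3a1 and Rpl30 fell while the near-identical processed pseudogenes Rps3a2, Rps3a3 and Gm12191 rose. Other matched copies fell with their parents: Gm7600 (-1.87) and Gm13408 (-1.44) of Rps3a1, and Rpl30-ps10 (-0.77) of Rpl30. Reads moved between the parent gene and the copies that rose are a candidate explanation. Their summed reads changed by 0.18 log2 units for Rps3a1 and 0.06 for Rpl30. Both lay inside the -0.14 to 0.80 of the other ribosomal protein genes. Copies that fell were left out of these sums. A general shift of reads to pseudogenes is argued against by a median difference of -0.05 between copy and parent over 571 pairs, although single copies such as Eif3s6-ps2 (3.44 above Eif3e) and Gm13453 (3.02 above its parent) also rose far above theirs. A strain difference in sequence between the groups stays open and was not tested, and it bears on whether the mice of both groups shared their genetic background.

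A hypothesis is that libraries with the same number come from animals of the same sex. At 3 of 3 numbers both groups showed the same pattern of Xist and the Y-linked gene Ddx3y at 1 FPKM or more: Ddx3y without Xist in replicate 1, both in replicate 2, and Xist without Ddx3y in replicate 3. Xist was at 0.03, 12.65 and 42.88 FPKM in control replicates 1, 2 and 3 and at 0, 17.46 and 53.41 FPKM in copper deficiency. The labels give no sex, and replicate 2 of each group would then hold animals of both sexes. The hypothesis was drawn from these same values, so their match between the groups does not test it.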
